A study of Mus musculus with 6 samples.

How the data were processed

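Total RNA from sorted cells was converted to biotin-labelled cRNA and measured on 1 array per sample, per the labels' protocols. Probe set and control names in the table are those of Affymetrix arrays. The table deposited by the authors gives the intensity of 45101 probe sets on 6 arrays, 3 per group, on a linear scale. These values were computed with MAS5 in R 2.14.2, per the submitters' processing notes, which also name limma without saying what it was used for; versions of MAS5 and limma are not given in the sources used here. MAS5 combines perfect-match and mismatch probes into 1 signal per probe set and scales each array. The deposited intensity values have a 2% trimmed mean of 100 on every array, so differences in total RNA content between the populations are not measured. Detection calls were not used here, and signals near the background are noisy on a log scale.

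Of 45037 probe sets other than controls, 34957 had 1 gene symbol in the platform annotation, 920 had several and 9160 had no listed gene. The first kind named 18201 genes. The Entrez IDs of 34754 of these probe sets matched the gene table of the GRCm38 annotation, which changed 0 symbols and was used for names and neighbouring genes alone. Signals under 1 were set to 1 and log2 was taken, with no further scaling. A probe set was tested if it exceeded the 40th percentile of its array on at least 3 arrays, which 27738 did. Each gene was represented by its tested probe set with the highest mean log2 signal, for 12047 genes. A group was called dim for a gene if its probe set did not exceed the 40th percentile on any of that group's 3 arrays. For such genes the text gives a bound, "at least N-fold", which is the brighter group's mean over the dim group's mean of, per array, the higher of the signal and the 40th percentile. With arrays left out, or with the spike-in batch as a block (below), dimness and bound were taken from the arrays compared.

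Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. In the same fit 23 lists of genes, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists with at least 3 tested members. Lists were also run with an estimated correlation and with fry. There were 13 genes held by more than 1 list. Genes were named in the text by a rule set in advance. It took the 12 largest differences each way among genes past the threshold whose groups did not overlap, 8 anchor genes (Neurog2, Lmx1a, Lmx1b, Foxa2, Corin, Th, Nr4a2, Pitx3), up to 3 members of each list past the threshold or else its 2 brightest, and Xist, Ddx3y, Eif2s3y and Nnt. This gave 62 tested genes, and members named beyond it were added to complete a count. By chance 10% of genes have groups of 3 that do not overlap, and 15.5% of tested genes did.

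The limma fit and the list test were tried on simulated arrays of 12047 genes with 200 changed, in 10 runs. Simulated values were independent and normally distributed. The filter, the choice of probe set, the spike-in batch and correlation between genes were not simulated, so the rates may not hold for the real arrays. The fit recovered 29.4% of 2-fold, 78.5% of 4-fold and 95.2% of 16-fold changes, with 7.29% of calls false. A shifted list of 20 further genes passed camera at an unadjusted p under 0.05 in 10 of 10 runs and an unshifted one in 0.

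Alternatives fixed before the data were examined were quantile normalization, centring each array on its median, no filter, a filter at the 60th percentile, log2 of the value plus 32, eBayes without a trend, the mean of a gene's probe sets, leaving out probe sets ending in _s_at, _x_at or _a_at, counting each probe set, the replicate number as a block, and leaving out each array in turn. The spike-in batch as a block, the 4 arrays of its higher side alone, and lists without shared members were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Array slide and scan batches were not analysed here.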

Results

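Messenger RNA levels were measured on microarrays in cells sorted by flow cytometry from the ventral midbrain of mouse embryos at day 12.5, when dopaminergic neurons are being born there. There were 2 groups of 3 arrays. The first held GFP-positive cells of a mouse line in which GFP reports the proneural gene Neurog2 (Ngn2), called positive here. The second held GFP-negative cells of a line in which GFP reports Lmx1a, a transcription factor of dopaminergic progenitors, called negative here. Per the series' design text, the first population holds most dopaminergic progenitors and the second served as a non-dopaminergic reference, with biological replicates in both. Per the labels, the positive arrays came from CD1/129 mice and the negative arrays from C57BL/6 mice, so strain, mouse line and sort gate coincided with the group on every array. Values are log2 fold changes, positive minus negative, with the standard error (SE) of the limma fit and n = 3 arrays per group. The number of arrays limits their precision. Average signals of a group, or of a set of control probe sets, are geometric means.

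Median signal lay between 18.1 and 25.5 on the 6 arrays, and every array had the same trimmed mean of 100. Log2 signals correlated across probe sets at 0.935 to 0.956 within the positive group, 0.915 to 0.921 within the negative group and 0.892 to 0.925 between groups. Positive replicates 1 and 2 stood apart in control probe sets. Hybridization spike-ins averaged 2523 and 2619 on these arrays, against 5537 on positive replicate 3 and 4687 to 7244 on the negative arrays. The 18S ribosomal RNA probe sets averaged 3713 and 3696 on them, against 7241 to 9276 on the other 4 arrays. The 3' to 5' signal ratio of Gapdh was lower on them, at 4.41 and 4.73 against 5.94 to 9.21. That of actin was slightly higher, at 1.16 and 1.15 against 0.969 to 1.14. This split is called the spike-in batch. Its lower side held positive arrays alone, so the within-batch comparison was positive replicate 3 against the 3 negative arrays, and the fit with the batch as a block gave the same fold changes. Both fits rest on that 1 positive array, which is assumed to vary like the other arrays. List p-values at the preset correlation come from the spread across genes, in these fits and in the main one. They do not measure replication over arrays. Without positive replicate 3, group and spike-in batch coincide, so that fit cannot tell them apart.

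**Figure D1:**
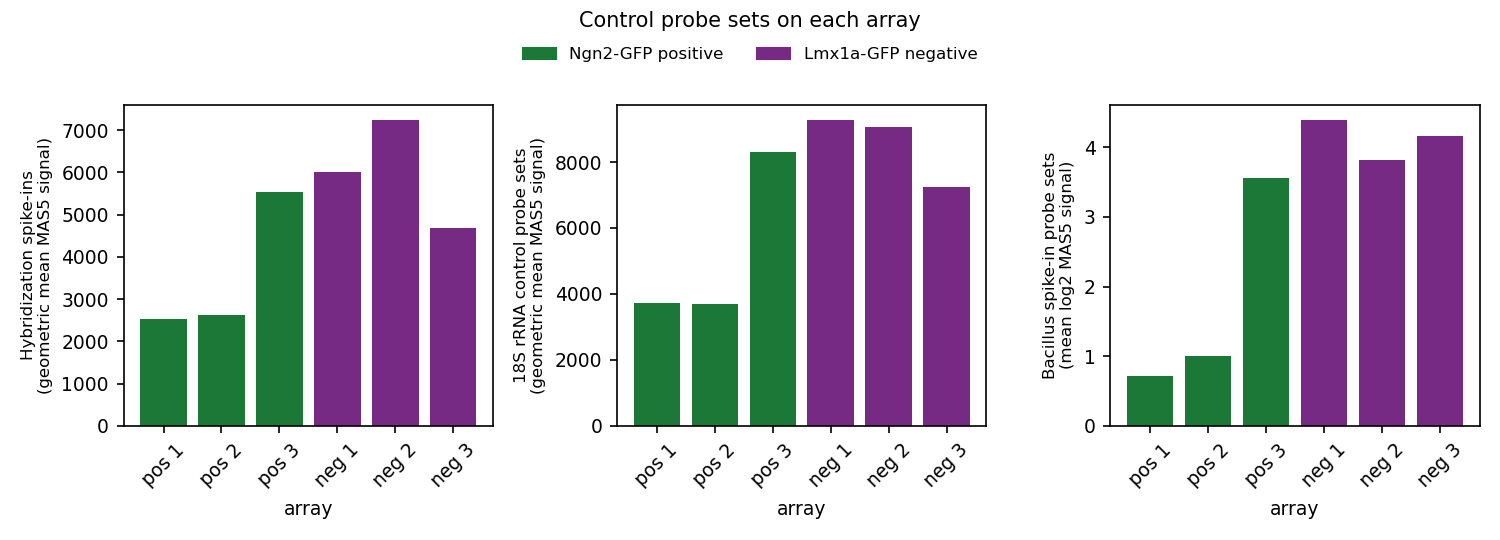
Bars show control probe sets on each of the 6 arrays. The panels give the geometric mean MAS5 signal of the hybridization spike-ins and of the 18S ribosomal RNA probe sets. The last panel gives the mean log2 signal of the Bacillus spike-in probe sets. Positive replicates 1 and 2 have the 2 lowest bars in each panel, with hybridization spike-ins at 2523 and 2619 against 4687 to 7244 on the other 4 arrays. The Bacillus values, at 0.72 to 4.39 (log2), lie near or under the 40th percentile of the arrays, a linear signal of 10.2 to 15.8. That panel thus shows values near background.

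The 2 genes whose reporters defined the sorted cells were examined first. Neurog2 averaged a signal of 591 in positive and 352 in negative cells, a log2 difference of 0.75 (SE 0.21) that did not pass the threshold (adjusted p = 0.155), although the 3 positive values all lay above the 3 negative ones. Lmx1a was higher in positive cells by 4.95 (SE 0.63, adjusted p = 0.00167). Its signal was dim on all 3 negative arrays, so the bound on the difference was at least 9.65-fold. Negative cells were sorted for lack of the Lmx1a reporter, so this direction was set by the gate and serves as a check of the labels. Among other genes of the floor plate and midbrain dopaminergic progenitors, Lmx1b differed by 1.05 (SE 0.26, adjusted p = 0.104), Foxa2 by 0.33 (SE 0.21, adjusted p = 0.597) and Corin, dim on all 3 negative arrays, by at least 1.41-fold (adjusted p = 0.288), none past the threshold. Pitx3, a transcription factor of dopaminergic neurons, stayed under the filter for dim probe sets, with signals of 1.01 to 2.39 on positive and 0.414 to 0.799 on negative arrays. With the spike-in batch as a block, Lmx1a was higher by at least 6.07-fold and no longer passed (adjusted p = 0.121), and Neurog2 differed by 0.51 (adjusted p = 0.833). Without positive replicate 3, where group and spike-in batch coincide, Neurog2 passed at 0.87 (adjusted p = 0.0444).

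Of 12047 genes tested, 128 differed between the populations, 51 higher and 77 lower in positive cells, and 126 of them by at least 2-fold (51 higher, 75 lower). At an unadjusted p under 0.05 there were 1296 genes. Of the 128 genes, 61 had other tested probe sets, 100 in all. Of these probe sets 93 had the sign of the brightest one and 7, in 6 genes, the opposite sign. Their differences could be smaller, as for Fam184b (0.54), Tfap2b (-0.65), Lhx1 (-0.72) and Klf4 (0.92), or larger, as for Cbln1 (2.48) and Hbb-bh1 (-8.62). The 12 genes with the largest fitted excess in positive cells included Lmx1a, Th (4.89, SE 0.69), the rate-limiting enzyme of dopamine synthesis, Slc35d3 (4.82, SE 0.79), Slc6a3, the dopamine transporter (4.20, SE 0.73), the zinc finger gene Bnc2 (4.05, SE 0.46), the receptor guanylate cyclase Gucy2c (3.81, SE 0.66), the Wnt signalling agonist Rspo2 (3.50, SE 0.56) and the phosphodiesterase Pde1a (3.50, SE 0.76). Micalcl (2.97), A930009L07Rik (2.78), Fam184b (2.77) and the synaptic vesicle protein gene Sv2b (2.61) completed the 12. Slc35d3, Slc6a3, Gucy2c, Rspo2 and Pde1a were dim on all 3 negative arrays, with bounds of at least 4.11-fold, 5.33-fold, 3.27-fold, 5.69-fold and 3.2-fold, so the fitted values of these genes and of Lmx1a set no order, and Th and Micalcl each exceeded the filter level on 1 negative array. The 12 genes with the largest fitted deficits were mostly genes of blood cells and macrophages, described further on, and included Clic5, at least 4.25-fold lower, and Tent5c, at least 7.83-fold lower.

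These counts depended on the arrays included. With the spike-in batch as a block, 34 genes passed (8 higher, 26 lower), of which 30 were among the 128, 6 higher and 24 lower. Within the higher spike-in batch alone, 38 genes passed (6 higher, 32 lower). Without positive replicates 1, 2 or 3 the count was 78, 58 or 419, and without negative replicates 1, 2 or 3 it was 85, 80 or 83. The count of 419 is of the fit in which group and spike-in batch coincide. Of the 128 genes, 46 passed in all 6 of these fits, 13 higher and 33 lower, including Lmx1a, Th, Bnc2, A930009L07Rik and Sv2b. Without positive replicate 1, adjusted p was 0.0994 for Slc35d3, 0.128 for Gucy2c, 0.284 for Pde1a and 0.181 for Micalcl, and without positive replicate 2 it was 0.159, 0.233, 0.279 and 0.299 for these genes and 0.0685 for Fam184b. Pde1a and Micalcl also missed the threshold without positive replicate 3 (0.0865 and 0.0781) and negative replicate 1 (0.0538 and 0.0786), Pde1a without negative replicate 2 (0.0746) and Micalcl without negative replicate 3 (0.0972). With the batch as a block, 11 of the 12 genes higher in positive cells lost the call and A930009L07Rik kept it (3.13, adjusted p = 0.0209). The differences, from 1 positive array, were then 4.38 for Th, 3.61 for Bnc2, 3.06 for Micalcl, 2.88 for Fam184b and 2.08 for Sv2b. For genes dim on the negative arrays the bounds were at least 6.07-fold for Lmx1a, 3.73-fold for Slc35d3 and 8.49-fold for Slc6a3. They were at least 2.84-fold for Gucy2c, 3.93-fold for Rspo2 and 3.2-fold for Pde1a.

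**Figure D2:**
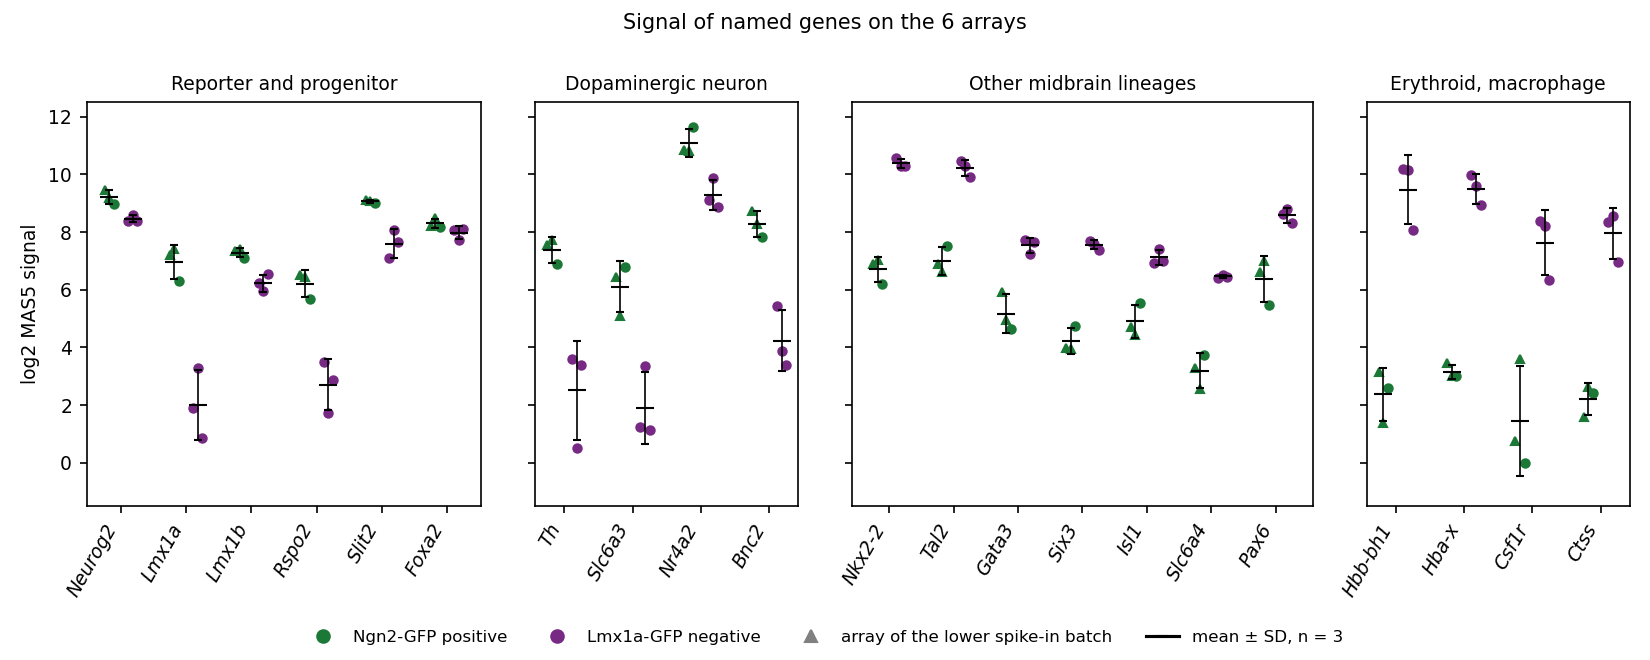
Points are the log2 MAS5 signal of each of the 6 arrays for named genes in 4 panels, with the mean and SD of 3 arrays per group in black and triangles for the 2 arrays of the lower spike-in batch. Th has a geometric mean signal of 168 in positive and 5.69 in negative cells, and Hbb-bh1 has 5.19 and 710.

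The negative cells were sorted for lack of the Lmx1a reporter and were the non-dopaminergic reference of the design. An excess of dopaminergic genes in positive cells was thus favoured by the gate and serves mainly as a check of the labels. Genes of dopaminergic neurons were the list with the clearest excess in positive cells. Of 15 tested members, 9 were higher and none lower (11 and 0 adjusted over the list alone), with a median log2 fold change of 1.41. They included Th, Slc6a3 and Bnc2. The count of 9 fell to 4, 4 and 7 without positive replicates 1, 2 and 3 and to 5, 7 and 4 without negative replicates 1, 2 and 3. Nr4a2, the nuclear receptor Nurr1, was higher by 1.80 (SE 0.30, adjusted p = 0.0093), at signals of 2174 and 624. The list of dopaminergic progenitor and floor plate genes had 5 of 16 tested members higher and 1 lower (9 and 2 adjusted over the list alone), with a median of 1.05, or 0.71 with dim genes at their bounds. Its higher members past the threshold were Lmx1a, whose direction the gate set, Rspo2, the axon guidance cue Slit2 (1.46, SE 0.25), En1 and Foxa1. The lower one was Otx2, a transcription factor of forebrain and midbrain (-1.06, SE 0.20). Without 1 array, 1 to 5 of its members were higher. The set test of the progenitor list included Lmx1a and was not run without it, so part of an upward shift was set by the gate. Both lists shifted upward by camera (adjusted p = 2.29e-15 and 2.65e-07), also with an estimated correlation (adjusted p = 0.0072 and 0.0311). With the batch as a block, which rests on 1 positive array, their medians were 1.54 and 1.06. With that block 1 neuron gene, Nr4a2, passed (2.35, adjusted p = 0.0139) and no progenitor gene did, with En1 at 1.07 (adjusted p = 0.236), Foxa1 at 1.19 (adjusted p = 0.208) and Otx2 at -1.12 (adjusted p = 0.215). Th differed by 4.38 (adjusted p = 0.176), Slc6a3 by at least 8.49-fold (adjusted p = 0.143), Rspo2 by at least 3.93-fold (adjusted p = 0.261) and Slit2 by 1.41 (adjusted p = 0.231). Adjusted p was 0.113 for Slc6a3 and 0.0741 for Rspo2 without positive replicate 1, 0.0912 for Rspo2 and 0.0573 for Slit2 without positive replicate 2, 0.0539 for Slc6a3 without positive replicate 3, and 0.0538 and 0.0597 for Nr4a2 without negative replicates 1 and 3. En1 had 0.0573 without positive replicate 2. Foxa1 had 0.149 and 0.0927 without positive replicates 1 and 2 and 0.127 and 0.0833 without negative replicates 1 and 3. Otx2 had 0.0664 and 0.145 without positive replicates 1 and 2 and 0.0608, 0.103 and 0.0527 without negative replicates 1, 2 and 3.

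Genes of neurogenesis were taken next. None of 18 tested proneural and neurogenic differentiation genes passed (3 higher adjusted over the list alone), with 15 at positive values and a median of 0.27. Without positive replicate 3, 3 of them were higher, and without negative replicate 3, 1 was. The brightest were Tcf12 at 0.45 (SE 0.23) and Insm1 at -0.56 (SE 0.21). Of 24 radial glia and Notch response genes, 2 were lower in positive cells and none higher (5 lower adjusted over the list alone), with 21 at negative values and a median of -0.55. The count of lower genes was 7 without positive replicate 3 and 1 without each other array. The lower ones were Pax6, a progenitor transcription factor (-2.22, SE 0.34, adjusted p = 0.00696), and Fabp7, a radial glial fatty acid binding protein (-1.18, SE 0.26, adjusted p = 0.0494). None of 31 cell cycle genes passed (median 0.20), with Mki67 at -0.32 (SE 0.23) and Mcm7 at 0.15 (SE 0.23), and none of 25 general neuronal genes did (median -0.04), with Tubb3 at -0.30 (SE 0.27) and Dcx at -0.45 (SE 0.28). Without positive replicate 3, 3 general neuronal genes were lower. By camera the proneural list shifted upward (adjusted p = 0.00156) and the radial glia list downward (adjusted p = 1.91e-07), both lost with an estimated correlation (adjusted p = 0.108 and 0.157), while the cell cycle and neuronal lists did not shift (adjusted p = 0.894 and 0.884). With the batch as a block, adjusted p was 0.0675 for the proneural list and 0.0097 for the radial glia list, whose median shrank to -0.23. The neuronal list then shifted upward (median 0.21, adjusted p = 0.0194), the cell cycle median was -0.09, Pax6 passed at -3.11 (adjusted p = 0.00267) and Fabp7 did not (-0.62, adjusted p = 0.374). Fabp7 passed in 1 of the 6 fits without an array, the one without positive replicate 3, at adjusted p of 0.252 and 0.326 without positive replicates 1 and 2 and 0.146, 0.166 and 0.168 without negative replicates 1, 2 and 3, and Tubb3 passed without positive replicate 3 (-0.58, adjusted p = 0.0451). In the fit without positive replicate 3, group and spike-in batch coincide.

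Among genes of other ventral midbrain and neighbouring lineages, the GABAergic list had the most members lower in positive cells. In the midbrain GABAergic list 7 of 15 tested members were lower and none higher (11 lower adjusted over the list alone), with a median of -1.45, or -0.99 with dim genes at their bounds. Without 1 array 5 to 8 were lower. The 7 were Tal2 (-3.21, SE 0.26), Six3 (-3.34, SE 0.33), Gata3 (-2.36, SE 0.35), Gata2, Tal1, Tfap2b and Gad1, which makes GABA. Nkx2-2, a transcription factor of ventral neural tube progenitors held in 3 lists, was lower by 12.8-fold (-3.67, SE 0.24, adjusted p = 4.80e-06). In the serotonergic list it and the serotonin transporter Slc6a4 (-3.27, SE 0.45), above the filter level on 1 positive array, were the 2 lower genes of 6 tested, with a median of -2.54, or -1.93 with dim genes at their bounds. In the oculomotor list Isl1, a motor neuron transcription factor (-2.22, SE 0.35), was the 1 lower gene of 4, with a median of -2.17, or -0.84 with dim genes at their bounds. The oculomotor list had 2 lower genes without positive replicate 3, and the serotonergic list had 3 without positive replicate 1. In the forebrain and diencephalic list Six3 and Barhl2 (-2.28, SE 0.37) were the 2 lower genes of 7, with a median of -0.74. In the red nucleus and Nkx6-1 domain list of 10 tested genes, Nkx2-2 and Lhx1 (-1.37, SE 0.22) were lower and Slc17a6, the vesicular glutamate transporter, was higher (1.11, SE 0.24), with a median of -0.08. Of the hindbrain list, Irx2 (-0.52, SE 0.23) and Gbx2 (-0.45, SE 0.58) were the 2 genes tested and neither passed, while 11 others were dim.

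All 5 of these lists with a set test shifted downward by camera, with adjusted p of 4.24e-15 for the GABAergic, 6.77e-06 for the serotonergic, 0.000711 for the oculomotor, 0.000711 for the forebrain and 0.0184 for the red nucleus list. With an estimated correlation the GABAergic list passed (adjusted p = 0.0072) and the others did not (adjusted p = 0.057 for the serotonergic, oculomotor and forebrain lists and 0.110 for the red nucleus list). With the batch as a block, Tal2 (-2.69), Six3 (-2.83), Gata3 (-2.90), Gata2 (-1.98), Nkx2-2 (-4.18) and Barhl2 (-2.85) passed, at adjusted p of 0.000117 to 0.0473. Gad1 (-1.22, adjusted p = 0.224), Tal1 (-0.86, adjusted p = 0.359), Tfap2b (-1.91, adjusted p = 0.556), Isl1 (-1.57, adjusted p = 0.304), Slc6a4 (-2.72, adjusted p = 0.155), Lhx1 (-1.23, adjusted p = 0.208) and Slc17a6 (0.63, adjusted p = 0.667) did not. Under that block the median was -1.22 for the GABAergic list and 0.01 for the red nucleus list, which lost its shift. Tal2, Six3, Gata3, Gata2, Gad1, Nkx2-2, Isl1 and Slc6a4 passed without any 1 array. Adjusted p was 0.0538 for Lhx1 without positive replicate 2 and 0.054 for Barhl2 without negative replicate 1. For Slc17a6 it was 0.23 and 0.295 without positive replicates 1 and 2 and 0.0782, 0.166 and 0.149 without negative replicates 1, 2 and 3. Tal1 had 0.128 and 0.19 without positive replicates 1 and 2 and 0.0647, 0.113 and 0.0867 without negative replicates 1, 2 and 3, and Tfap2b had 0.114 without positive replicate 2 and 0.151, 0.176 and 0.081 without these negative arrays.

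**Figure D3:**
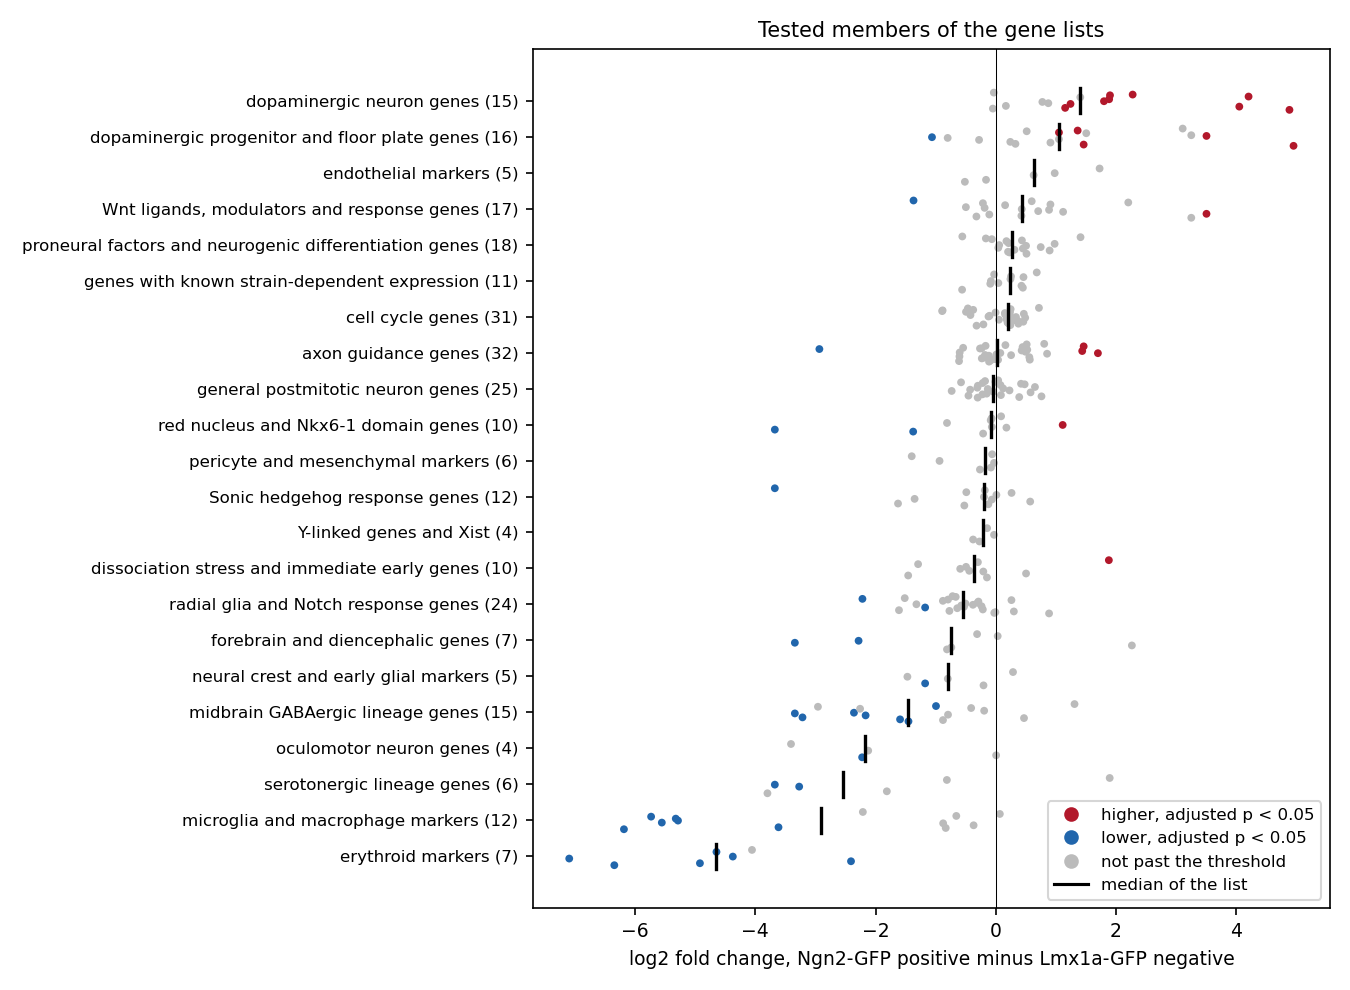
Each point is the log2 fold change, positive minus negative, of 1 tested gene, by gene list, with red and blue for genes higher and lower at adjusted p under 0.05, grey for the others and a black bar at the median of the list. The median is 1.41 for dopaminergic neuron genes, -1.45 for midbrain GABAergic genes and -4.65 for erythroid markers.

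Signalling and guidance genes went both ways. Among 17 tested Wnt pathway genes, Rspo2 was higher and Sfrp2, a secreted Wnt antagonist, was lower (-1.37, SE 0.27, adjusted p = 0.0311), with 5 higher and 1 lower adjusted over the list alone and a median of 0.43. Among 12 Sonic hedgehog response genes, Nkx2-2 was the 1 lower gene and none was higher (1 lower adjusted over the list alone), with a median of -0.19. Among 32 axon guidance genes, Alcam, a cell adhesion molecule (1.70, SE 0.23, adjusted p = 0.00303), Slit2 and Nrp2 were higher and the netrin receptor Unc5b was lower (-2.93, SE 0.27, adjusted p = 8.74e-05), with 3 higher and 1 lower adjusted over the list alone and a median of 0.02. By camera the Wnt list shifted upward (adjusted p = 0.0364) and the hedgehog list downward (adjusted p = 0.00457), both lost with an estimated correlation (adjusted p = 0.157 and 0.0793), and the axon guidance list did not shift (adjusted p = 0.217). With the batch as a block, Unc5b (-3.41, adjusted p = 0.00159) and Alcam (1.87, adjusted p = 0.0415) passed, Nrp2 (1.43, adjusted p = 0.0754), Slit2 (1.41, adjusted p = 0.231), Rspo2 (at least 3.93-fold, adjusted p = 0.261) and Sfrp2 did not (-1.04, adjusted p = 0.556), the Wnt list lost its shift (adjusted p = 0.144) and the axon guidance list shifted upward (adjusted p = 0.0403). The Wnt list had an adjusted p of 0.0601, 0.0509 and 0.0846 without positive replicates 1, 2 and 3 and 0.069 without negative replicate 3, and the axon guidance list had 0.0499 without negative replicate 2. Adjusted p for Sfrp2 was 0.0806 and 0.172 without positive replicates 1 and 2 and 0.0779, 0.128 and 0.0867 without negative replicates 1, 2 and 3, and for Slit2 it was 0.0573 without positive replicate 2.

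The largest fitted differences were in markers of blood cells and macrophages, of which 12 of 19 tested were lower in positive cells and none higher. Of 7 tested erythroid markers, 6 were lower (7 adjusted over the list alone), with a median of -4.65. The embryonic globin genes Hbb-bh1 (-7.10, SE 0.57) and Hba-x (-6.35, SE 0.32) were dim on all 3 positive arrays, which put them at least 55-fold and 56.2-fold lower, and Hbb-b2, outside the list, had -5.50 (SE 0.32, adjusted p = 2.07e-06). Alas2, the erythroid enzyme of haem synthesis, was lower too (-4.92, SE 0.96) and exceeded the filter level on 1 positive array. Globin genes have similar sequences, so their probe sets may not separate them. Of 12 tested microglia and macrophage markers, 6 were lower and none higher (7 lower adjusted over the list alone), with a median of -2.91, or -1.39 with dim genes at their bounds. Cd68 (0.07), Lyz2 (-0.37) and Fcgr3 (-0.66) were among the 6 that did not pass. The lower ones included the growth factor receptor Csf1r (at least 15.4-fold lower), the protease Ctss (at least 19.2-fold lower), Aif1 (at least 3.64-fold lower), Tyrobp (at least 11.5-fold lower) and Laptm5 (-5.32, SE 0.37, above the filter level on 1 positive array), and Ly86, outside the list, was at least 3.81-fold lower. These values are of the brightest probe sets. Other Csf1r probe sets fell less, at -1.97 and -2.33 (log2), as did another of Laptm5 (-1.53). Another of C1qb, also lower, fell more (-4.53 against -3.61). Both lists shifted downward by camera (adjusted p = 7.75e-23 and 1.06e-14) and with an estimated correlation (adjusted p = 0.0072 and 0.0161). With the batch as a block, which rests on 1 positive array, their medians were -4.25 and -3.71.

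With that block Hbb-b2 passed, as did genes dim on positive replicate 3, namely Hbb-bh1 (at least 61.4-fold lower), Hba-x (62.6-fold), Csf1r (17.2-fold), Ctss (21.4-fold), Laptm5 (40.4-fold), Tyrobp (12.8-fold) and Tent5c (8.73-fold). Alas2 (-2.33, adjusted p = 0.623) did not, nor did the dim Aif1 (at least 4.06-fold, adjusted p = 0.224), Ly86 (4.25-fold, adjusted p = 0.157) and Clic5 (4.74-fold, adjusted p = 0.169). Without negative replicate 1, adjusted p was 0.123 for Aif1, 0.0821 for Ly86 and 0.0593 for Tent5c. Without negative replicate 2 it was 0.122 for Aif1, Ly86 and Clic5 and 0.0699 for Tent5c, and without negative replicate 3 it was 0.131 for Clic5. Alas2 had 0.0533 and 0.0835 without positive replicates 1 and 2 and 0.137, 0.134 and 0.0797 without negative replicates 1, 2 and 3.

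Markers of endothelial, pericyte and mesenchymal cells lay mostly near the filter level. The signal of the 11 tested in negative cells had a median ratio of 1.63 to the filter level of the positive arrays, so most could show little of a fall. None of 5 tested endothelial markers passed (median 0.63, or -0.54 with the batch as a block), with Egfl7 at 0.63 (SE 0.50) and Eng at -0.51 (SE 0.67), and 13 others were dim. None of 6 pericyte and mesenchymal markers passed (median -0.17), with Postn at -0.06 (SE 0.31) and Col1a2 at -0.08 (SE 0.43), and 12 others were dim. Of 5 neural crest and early glial markers 1 was lower, Fabp7, which is also in the radial glia list (1 lower adjusted over the list alone, median -0.80). Of 10 stress and immediate early genes, Klf4 was higher (1.88, SE 0.35, adjusted p = 0.0209) and none lower (1 and 0 adjusted over the list alone), with a median of -0.37, or 0.22 with the batch as a block. Without positive replicate 3, 1 gene of this list was higher and 2 were lower. By camera the crest and glial list shifted downward (adjusted p = 0.0364), lost with an estimated correlation (adjusted p = 0.157), and the endothelial (0.39), pericyte (0.313) and stress (0.319) lists did not shift. The crest and glial list had an adjusted p of 0.0115 with the batch as a block, 0.0701 and 0.0846 without positive replicates 2 and 3, and 0.0543 and 0.108 without negative replicates 1 and 3. Klf4 did not pass with the block (1.94, adjusted p = 0.238), nor without positive replicates 1 and 2 (0.0849 and 0.17) or negative replicate 1 (0.059).

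Genes that track the sex mix and the strain of the embryos did not pass the test. Xist, expressed from the inactive X chromosome, differed by -0.27 (SE 0.24, adjusted p = 0.705), the Y-linked Eif2s3y by -0.03 (SE 0.24, adjusted p = 0.981) and Kdm5d by -0.14 (SE 0.32, adjusted p = 0.895), with no probe set naming Ddx3y alone. None of 4 genes of this list passed, and the list did not shift (adjusted p = 0.345). A different sex mix would move Xist and the Y-linked genes in opposite directions, which a test for a shared direction cannot show. None of 11 tested genes with known strain-dependent expression passed (median 0.24), and the list did not shift by camera (adjusted p = 0.293). Its members need not share a direction, so that test could miss a strain difference. Nnt, which carries a deletion in C57BL/6J mice, was at -0.56 (SE 0.30, adjusted p = 0.513) and Glo1 at 0.45 (SE 0.21). The Nnt signal averaged 2256 in positive and 3326 in negative cells, which were C57BL/6, and the groups overlapped. Nnt passed without positive replicate 3, where group and spike-in batch coincide (adjusted p = 0.0113), and differed by 0.16 with the batch as a block. With the preset correlation, 14 of 22 lists tested as a set passed, and 5 did with an estimated one, namely the dopaminergic neuron, dopaminergic progenitor, GABAergic, erythroid and macrophage lists.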

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

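The examples were chosen after the values were seen, and no explanation was tested for them. Among 4561 tested probe sets that have no single gene symbol in the annotation used here, and which no comparison of genes covers, 5 were higher and 9 lower in Ngn2-GFP positive cells. Of those above the filter level on at least 1 array of each group, the one with the largest excess in positive cells had a log2 fold change of 3.49 (SE 0.34, adjusted p = 0.000165), with signals of 138, 164 and 181 on the positive arrays and 15.6, 12.8 and 14.5 on the negative ones, 1 of them above the filter level. The one with the largest deficit had -6.55 (SE 0.76, adjusted p = 0.000775), with signals of 0.683, 8.65 and 16.3 on the positive arrays, 1 of them above the filter level, and 384 to 558 on the negative ones.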

How the results depend on the processing

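The spike-in batch block, the 4-array comparison and the lists without shared members were chosen after the data were seen. The dopaminergic neuron, dopaminergic progenitor, GABAergic, erythroid and macrophage lists kept their direction and passed under all alternatives run. With the batch block and the 4 arrays this rests on 1 positive array and does not measure replication. For the dopaminergic lists the upward direction was favoured by the gate. Groups did not overlap for any of the 128 genes, so their sign could not turn with arrays left out or the batch block; it turned for 1 gene each with the mean of probe sets (127 of 128 kept) and without _s_at, _x_at and _a_at probe sets (109 of 110). Against 51 higher and 77 lower genes, 3 and 16 passed without a filter (18201 genes tested, all 19 among the 128) and 15 and 27 with eBayes without a trend (34 among the 128), the same counts holding at 2-fold. With the spike-in batch as a block 8 and 26 passed and with the 4 arrays 6 and 32, also at 2-fold. With 1 array left out, higher genes ranged from 15 to 85 and lower genes from 43 to 334 (at 2-fold 15 to 77 and 43 to 175). The highest counts came without positive replicate 3, where group and spike-in batch coincide. The median difference of all genes stayed within 0.1 under each scaling, at 0.01 with quantile normalization and -0.01 with centring, against 0.03. Lmx1a missed the threshold without a filter (4.95, adjusted p = 0.0656), and with the batch block or the 4 arrays (4.29 each, at least 6.07-fold, adjusted p = 0.121 and 0.741), over a range of 3.9e-05 to 0.741 in the alternatives; without 1 array it lay between 4.37 and 5.59 (bounds 8.28-fold to 12.2-fold) and Neurog2 between 0.62 and 0.87, the latter passing without positive replicate 3. The neuronal list turned upward with quantile normalization (adjusted p = 0.0416), the batch block (0.0194) and the 4 arrays (0.0251). The Wnt list missed the threshold without a filter (0.0575), at the 60th percentile (0.246), without _s_at, _x_at and _a_at probe sets (0.0826), with the batch block (0.144) and with the 4 arrays (0.229), and spanned 0.021 to 0.0846 with arrays left out. The crest and glial list missed it without _s_at, _x_at and _a_at probe sets (0.0818) and spanned 0.00808 to 0.108 with arrays left out. The axon guidance list passed with the mean of probe sets (0.0385), the batch block (0.0403) and the 4 arrays (0.0487) and spanned 0.0499 to 0.536. With the batch block and the 4 arrays the proneural list (0.0675 and 0.0737) and the red nucleus list (0.184 and 0.127) missed it. With an estimated correlation 5 lists passed in place of 14, and adjusted p was 0.108 for the proneural, 0.157 for the radial glia, Wnt and crest, 0.11 for the red nucleus, 0.057 for the oculomotor, serotonergic and forebrain and 0.0793 for the hedgehog list. Without members shared with another list 9 passed, and the red nucleus (0.749), forebrain (0.254), hedgehog (0.143), Wnt (0.599) and crest (0.353) lists missed it. Nkx2-2, Six3, Rspo2 and Fabp7 were among the 13 shared genes left out, and the part of each was not tested. By fry the radial glia (0.0775) and crest (0.0732) lists missed it and the strain list passed (0.00865). With the replicate number as a block 47 higher and 80 lower genes passed, 114 of them among the 128; deviations of same-numbered arrays correlated at 0.14, -0.10 and 0.03 and not every array correlated best with its own number, so the numbers were not treated as pairs. The oculomotor, endothelial, pericyte and crest lists had fewer than 3 tested members at the 60th percentile and got no test there. Fitted values of dim genes such as Lmx1a lean on signals near background, so the bounds stand beside them. The cause of the changes with scaling, trend and batch terms was not tested.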

Other observations

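The genes in the first 2 paragraphs, and the tests of strain, of vascular markers, of the second Rps9 probe set, of matched genes for the blood and macrophage markers and of the calls under the spike-in batch block, were chosen after the results were seen. Of the 128 genes, 81 were in no list, and those named next passed without any 1 array. Higher in Ngn2-GFP positive cells were Cbln1, which encodes a secreted synapse organizer (log2 fold change 2.02, SE 0.20, adjusted p = 0.000158), and the transcription regulators Skor1 (1.79, SE 0.26) and Ebf2 (1.45, SE 0.21). C130021I20Rik, a long non-coding transcript that neighbours Lmx1b in the gene table, was higher by 2.40 (SE 0.19, adjusted p = 2.81e-05) at signals of 1176 and 223, while Lmx1b itself did not pass. With the spike-in batch as a block Cbln1 (2.11), Skor1 (2.38) and C130021I20Rik (2.39) passed, and Ebf2 did not (1.25, adjusted p = 0.164).

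Lower in positive cells were the neuropeptide gene Nts (-3.50, SE 0.35, adjusted p = 0.000182, above the filter level on 1 positive array), the transcription factor gene Meis2 (-2.93, SE 0.35), the growth factor binding protein gene Igfbp5 (-1.69, SE 0.25) and Phgdh, an enzyme of serine synthesis (-1.96, SE 0.29). With the batch as a block Nts (-3.24, adjusted p = 0.0192) and Igfbp5 (-2.13, adjusted p = 0.012) passed, and Meis2 (-2.51, adjusted p = 0.0874) and Phgdh (-1.62, adjusted p = 0.228) did not.

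The 128 genes that differed could in part reflect the spike-in batch, DNA linked to the reporters, or strain. With the batch as a block, which rests on 1 positive array and takes its spread from the other arrays, 30 passed, the median ratio of blocked to unblocked fold change over all 128 was 0.962 (genes chosen with that array, which favours a ratio near 1), and for the 98 others the median size went from 1.73 to 1.53 (log2) while the median SE went from 0.30 to 0.42. Among 369 to 427 genes called from the lower-batch arrays against 2 negative arrays, the difference between held-out arrays had a median of -0.017, 0.341 and -0.025 of the fold change. The sign was kept by 48.8%, 84.1% and 48.5% of these genes, with negative replicates 1, 2 and 3 held out. With 1 positive array on the higher side, batch and group cannot be told apart beyond that array. Against linked DNA as the main cause, 4 of the 128 lay among the 100 tested genes nearest each reporter locus, 0 at Lmx1a and 4 at Neurog2 (Ntng1, S1pr1, Slc39a8 and Ddit4l), where 1.06 were expected (one-sided Fisher's exact test p = 0.0218), so a part near Neurog2 stays open. Strain stays open too, since 0 of 11 strain genes passed but strain and group coincide on each array, as does the difference between dopaminergic and other lineages named by the design. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05; for genes, genes at 2-fold and lists, 1 of 10 reached the real values of 128, 126 and 14, and the highest of the others were 0, 0 and 6.

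Lower erythroid and macrophage markers may come from blood cells and macrophages in the GFP-negative gate, which a gate for GFP-positive cells would remove. Of 11 members visible in negative cells (above the filter level on at least 2 arrays) and not past the threshold, 10 (90.9%) were also lower in positive cells. The share was 51.8% for other genes matched on their level in negative cells (markers of a cell type move together, so no p is given). Of these lists 1 erythroid and 6 macrophage markers were tested and did not pass, so some of the 11 were never tested. Untested ones exceeded the filter level on fewer than 3 arrays, so their direction leans on signals near background. Among markers past the threshold Hbb-y, the brightest, averaged 9337 in negative and 373 in positive cells. A loss of all non-neural cells alike stays open. The 11 endothelial, pericyte and mesenchymal markers tested had a median of -0.08, with a 95% interval of -0.51 to 0.63 from a bootstrap over markers. This interval treats markers as independent and does not measure spread between arrays. With the batch as a block, which rests on 1 positive array, the median was -0.54. But 25 others were dim, and 1 of the 11, Postn, was bright enough in negative cells to show a 4-fold fall above the filter level. No gene of these lists is known here to be free of expression in the neural tissue, and a difference in dissection between the lines was not tested.

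The ribosomal protein gene Rps9 was lower in positive cells on its brightest probe set (-3.72, SE 0.33, adjusted p = 5.98e-05), with signals of 413 and 5455. A candidate explanation is a sequence effect in that probe set, since the other bright one differed by -0.37 (SE 0.20). Against a general fall of ribosomal protein mRNA as large as this, 40 other such genes had a median of -0.32. The 95% interval of a bootstrap over genes was -0.39 to -0.28, which does not measure spread between arrays. These genes were thus lower too, by about as much as the other bright Rps9 probe set. A strain variant under the probes and a transcript sharing its sequence were not tested.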
